A study of Mus musculus with 7 samples.

How the data were processed

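CD11b-enriched cells of naive and LLC-tumor-bearing C57/Bl6 mice were profiled in 7 libraries, 3 from naive mice (blood, bone marrow, spleen) and 4 from tumor-bearing mice (the same tissues and the tumor tissue). Each library was 1 group, and its group came from its tissue and disease state in the labels. Per the labels' protocols, RNA and antibody-derived tag (ADT) libraries were made from single cells on a Chromium instrument with 3' chemistry. Magnetic enrichment and staining with oligo-tagged antibodies are stated in the series design text. Cell Ranger and the mouse build mm10 are named in the submitters' processing notes. The Cell Ranger version, the gene annotation and the filters on cells are not given in the sources used here.

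The authors deposited UMI counts per gene and cell (25127 genes, 4290 cells) and ADT counts for 47 antibodies in the same cells. Their metadata listed 4527 cells, each with its library, total counts, cluster and, per the file headers, a mitochondrial fraction, which the authors gave as a fraction of a cell's UMIs. The 237 cells of the metadata without counts entered no expression comparison. They held all cells of clusters 14, 15 and 18. The authors also deposited normalized ADT values, which equalled the natural log of 1 plus the ADT counts per 10000 of a cell. Their normalized RNA values were not used here. Totals per cell in the metadata equalled the sums of the counts in all cells, the smallest cell held 854 UMIs and the highest mitochondrial share was 9.86%, so no further filter was applied. No doublet caller was run. Leaving out the 2% of cells with the most UMIs in each library was the alternative for doublets.

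Clusters were the authors' own, at resolution 1, with 19 clusters of which 16 had counts. A cluster was called after a cell type only from 16 marker sets fixed before the data were examined, when at least 3 markers of that type stood among its 10 leading genes by fold (pseudo-count of 10 CPM). This named clusters 4 (monocyte-like), 11 (macrophage-like), 12 (neutrophil-like) and 17 (like conventional dendritic cells). Clusters 0 and 6, which met the number for neutrophils and B cells, were left unnamed after their leading genes were seen, since monocyte genes stood beside granule genes in cluster 0 and dendritic cell genes beside immunoglobulin genes in cluster 6. A cluster with more than 90% of its cells from 1 library is described as such. The plan was to compare neutrophils, monocytes, macrophages and dendritic cells as classes where both libraries held at least 50 cells of a class. No class of neutrophils, macrophages or dendritic cells reached that number in both libraries of a comparison. Monocytes could not be compared as 1 class of clusters, since only cluster 4 was named monocyte-like. Monocytes called 1 by 1 reached 50 cells in every library, and were compared as an alternative only. All counted cells of each library were compared instead, and clusters by number in blood and spleen, a choice made after the data were seen.

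UMIs were summed over the cells of a library and scaled to counts per 1000000 UMIs of that library (CPM). The comparisons were tumor-bearing over naive in blood, bone marrow and spleen, and tumor tissue over tumor-bearing blood, spleen and bone marrow. With 1 library per group there was no test, p-value or standard error. A gene was measured with at least 30 UMIs in the 2 libraries together and 20 CPM in one, and counted as higher or lower at 2-fold or more. Under an alternative or in 1 cluster, a call also ended where a gene fell under these minimums, whatever its fold. An ended call therefore need not mean a smaller ratio. Folds carry an exact 95% Poisson (conditional binomial) interval and shares an exact 95% Clopper-Pearson interval. These cover counting error only and are too narrow for genes whose UMIs sit in few cells. A fold against 0 UMIs is given as a lower bound at a floor of 3 UMIs in that library, which is 0.144 CPM in tumor tissue and 4.86 in tumor-bearing bone marrow. Log2 ratios of lists, of ranked genes and of genes in the closing section used a pseudo-count of 1 CPM, and folds did not, so the log2 of a fold differs from the log2 ratio. The size rule, the comparisons, 26 gene lists and the rule for named genes were set before the data were examined.

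Named genes were the 8 highest and 8 lowest log2 ratios of a comparison among genes past the size rule, and the same over the genes past it in all 3 tissues. From each list up to 4 members with the largest ratio were eligible. Mitochondrial, ribosomal-protein, haemoglobin, immunoglobulin and sex-linked genes and unnamed gene models were left out of the ranking. Antibodies of 2-fold or more were named, and otherwise the 3 with the largest ratio. Other genes named were chosen after their values were seen. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries. Antibodies were compared as shares of a library's summed ADT counts. No isotype control stood among the antibodies, so background binding was not removed. Members of the families of Bcl2a1, Ear2, Ifit3 and Stfa2l1 share sequence, and the counting could divide their reads. The strand setting of the counting was not given in the sources used here, so Plxna4os1 may hold reads of its sense partner.

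The steps were tested on simulated data, drawn from the real means and library sizes for 25127 genes with 200 changed. Of genes changed 3-fold, 100% were called on the right side in blood and in spleen, 92.5% in bone marrow and 98.5% in tumor tissue against blood. Of genes changed 1.5-fold, 7.46% passed 2-fold in bone marrow and 0% in blood. Intervals held the true value for 95.1% of genes in blood and 95.8% in bone marrow. Simulated counts were Poisson draws, the model of the intervals, so this coverage does not speak for UMIs clumped in few cells. Libraries with no difference were drawn 100 times per comparison, also as Poisson counts from library sums without differences between cells. Coordinates are from the GENCODE annotation of GRCm38, the assembly also called mm10, counted from 1, where 214 of 215 named genes were found by symbol. Each range spans the whole gene, and no part of a gene such as an exon or UTR was compared.

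Alternatives were TMM factors (edgeR 4.0.16 in R 4.3.3, used for these factors only), median-of-ratios size factors, totals without mitochondrial, ribosomal-protein and haemoglobin genes, means over cells of UMIs per 10000, cells thinned to 5000 UMIs, minimums of 100 UMIs and 50 CPM or none, cells called monocytes 1 by 1 from the marker sets, the largest cluster, 20 bins and 1.5-fold for agreement. For shares they were another denominator and cells called 1 by 1, and for antibodies raw counts and the deposited normalized values. Added after the data were seen were leaving out cluster 12, leaving out tumor tissue cells of clusters 11, 13 and 17, equal mixes of clusters, antibody counts divided by the median ratio, all cells of the metadata as denominator, and leaving out the cell with the most UMIs of a gene in the library where it stood higher. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.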

Results

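CD11b, an integrin chain carried by neutrophils, monocytes, macrophages and some dendritic cells, was the handle for enriching myeloid cells from C57/Bl6 mice, and RNA and surface antibody tags were then read in the same cells. The design contrasted naive mice with mice carrying LLC tumors, a transplantable Lewis lung carcinoma, at day 14. Blood, bone marrow and spleen were sampled in both states and the tumor tissue in tumor-bearing mice, which gave 7 libraries. Each tissue and state was 1 library, so no difference below had a replicate check, and the labels did not say which tissues came from the same animals. Gene counts were held for 4290 cells. They came to 814 cells in naive blood, 354 in tumor-bearing blood, 153 in naive bone marrow, 57 in tumor-bearing bone marrow, 416 in naive spleen, 579 in tumor-bearing spleen and 1917 in tumor tissue. Total unique molecular identifiers (UMIs, counted molecules) per library ran from 617821 in tumor-bearing bone marrow to 20844058 in tumor tissue. The other totals were 9776945 in naive blood, 4523693 in tumor-bearing blood, 1540719 in naive bone marrow, 4422486 in naive spleen and 5752217 in tumor-bearing spleen. Median UMIs per cell lay between 8841 in tumor tissue and 12445 in tumor-bearing blood, and the median share of mitochondrial UMIs between 2.85% and 3.46%. Levels are counts per 1000000 UMIs of a library (CPM). Ranges in parentheses after folds and shares are 95% intervals that cover counting error only.

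Cells of the tumor tissue formed a population apart from those of blood, bone marrow and spleen. In the authors' clustering, 9 clusters drew more than 90% of their cells from tumor tissue and held 1909 of its 1917 cells (99.6%, 99.2 to 99.8). The same clusters held 3 of 814 cells in naive blood, 3 of 354 in tumor-bearing blood and 0 of 416 in naive spleen. With 1 library of tumor tissue, such clusters may be that library rather than cell types, so they are given by number and leading genes. Cluster 3 was led by Spp1 and Arg1, cluster 5 by Cxcl9 and Gbp2, cluster 7 by Thbs1 and Ptgs2, cluster 8 by Ccl7 and Ccl2, and cluster 10 by the interferon-induced Rsad2, Cxcl10 and Ifit1. Cluster 9 was led by Dmkn and Nfil3. Cluster 13, with a median of 1477.5 UMIs per cell, was led by the collagen gene Col3a1 and the heat shock gene Hspa1a. A macrophage-like cluster (11; the complement genes C1qa and C1qc, the folate receptor gene Folr2 and the mannose receptor gene Mrc1) made up 6.99% of tumor tissue cells. Its cells held a median of 29673 UMIs, against 8841 in tumor tissue, so they weigh more in summed UMIs than by their number. A cluster like conventional dendritic cells (17; H2-Eb1, Cd209a) made up 2.87%.

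In blood and spleen the cells were spread over the unnamed clusters 0, 1, 2, 6 and 16, the monocyte-like cluster 4 and the neutrophil-like cluster 12. Called 1 by 1 from the marker sets, 94.1% to 98.2% of the counted cells of blood, bone marrow and spleen were monocytes. Neutrophils made up 1.72% to 4.52%. The comparisons of these tissues below thus describe mostly cells called monocytes. Cluster 4, led by the non-classical monocyte genes Eno3, Ear2, Ace, Spn and Treml4, held 16.22% of naive and 18.1% of tumor-bearing blood cells, 15.9% and 12.95% of spleen cells, and 0.654% and 3.51% of bone marrow cells. It held 0.156% of tumor tissue cells. The neutrophil-like cluster 12, led by Retnlg, S100a8, S100a9 and Ngp, held 11 of 814 (1.35%, 0.676 to 2.41) naive blood cells and 17 of 354 (4.80%, 2.82 to 7.58) tumor-bearing blood cells. In bone marrow it held 14 of 153 (9.15%, 5.09 to 14.9) naive and 1 of 57 (1.75%, 0.0444 to 9.39) tumor-bearing cells. Its shares in spleen were 3.85% and 3.97%, and 0.0522% in tumor tissue. These shares follow the magnetic enrichment and the authors' cell filters, and the leading genes of clusters 4 and 12 differed between some of the libraries, so no direction is drawn from them. Cluster 0, which mixed monocyte genes (F13a1) with neutrophil granule genes (Mmp8, Camp), held 24.6%, 27.4%, 48.4%, 54.4%, 22.8% and 18.8% of the cells of naive and tumor-bearing blood, bone marrow and spleen in that order. Cluster 6, which mixed the immunoglobulin gene Igkc with the dendritic cell gene Cd209a, held 14.5%, 10.7%, 7.84%, 3.51%, 12.3% and 12.4%. In tumor tissue both held 1 cell (0.0522%).

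**Figure D1:**
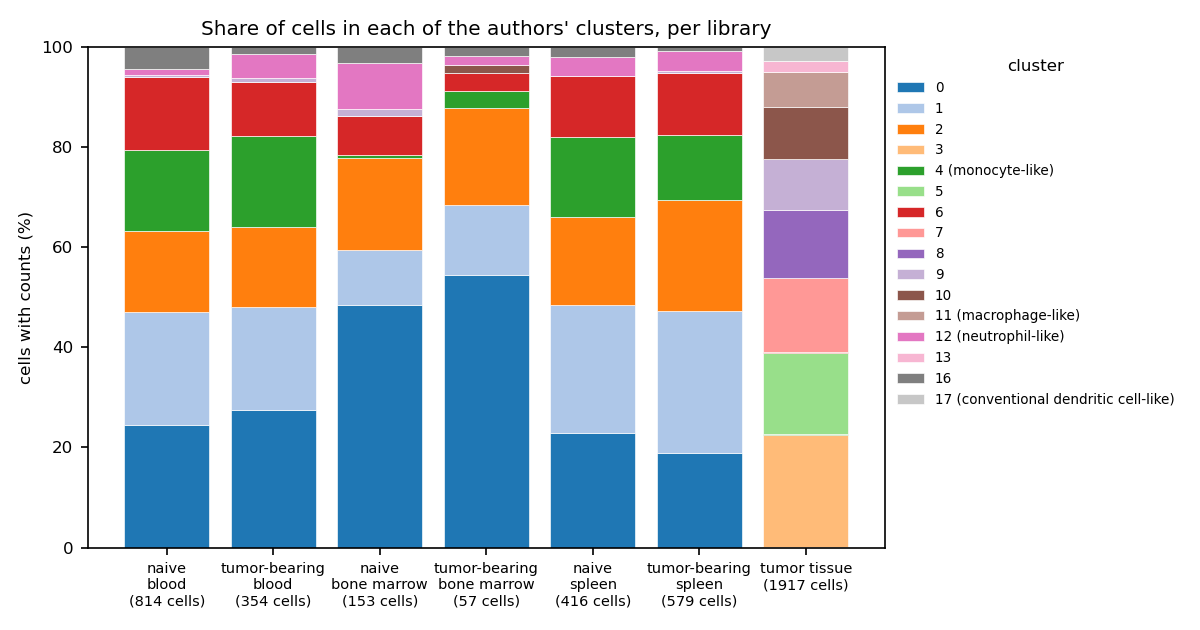
Share of counted cells (percent, vertical axis) of each of the 7 libraries in each of the authors' clusters, stacked by color. The 9 clusters mostly from tumor tissue fill 99.6% of that library's bar, and the neutrophil-like cluster 12 takes 1.35% of the naive and 4.80% of the tumor-bearing blood bar.

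The first comparison asked how the counted blood cells, mostly called monocytes, differed between tumor-bearing and naive mice. In tumor-bearing blood 5 of 13 measured genes of secondary and tertiary granules and 1 of 2 of primary granules stood at least 2-fold higher, along with other secreted and membrane protein genes. Lcn2, the iron-siderophore-binding lipocalin of specific granules (GRCm38 chromosome 2, 32384633 to 32388252), was 9.39-fold (7.80 to 11.4) higher, at 134 against 14.2 CPM. Wfdc21 was 8.81-fold (6.85 to 11.5) higher, Lrg1, a secreted leucine-rich glycoprotein (chromosome 17, 56119678 to 56122001), 7.34-fold (5.58 to 9.77), and Ifitm1, an interferon-inducible membrane protein (chromosome 7, 140967221 to 140969825), 6.22-fold (5.13 to 7.56). Vcan, the matrix proteoglycan versican, was 3.89-fold (3.42 to 4.42) higher and S100a8, a calcium-binding alarmin, 3.01-fold (2.90 to 3.11). Lpl, encoding lipoprotein lipase (chromosome 8, 68880491 to 68907448), was 4.05-fold (3.20 to 5.18) lower, and Cd209a, a C-type lectin of monocyte-derived dendritic cells, 3.02-fold (2.25 to 4.12) lower.

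Of 5300 genes measured in blood, 30 were at least 2-fold higher and 7 at least 2-fold lower, where simulated libraries with no difference gave 0. Those simulations held counting error only, without differences between cells, so 0 is not the number of calls that sampling of cells could give. Ngp, a granule protein gene, was 165-fold (45.0 to 1378) higher and the chemokine gene Ccl5 3.95-fold (3.001 to 5.24), but 1 cell held 150 of 153 Ngp UMIs and another 143 of 150 Ccl5 UMIs. One cell also held 2577 of the 7623 S100a8 UMIs, and without it the fold was 1.998, just under the threshold. In the largest cluster alone the calls of Ngp, Ccl5 and S100a8 also ended, as did that of Ngp without cluster 12 and among cells called monocytes 1 by 1. With the top cell of each gene left out, 16 of the 30 and 4 of the 7 stayed past 2-fold, among them Lcn2, Lrg1, Ifitm1, Wfdc21, Vcan, Chil3, Mmp8, Prtn3, Lpl and Cd209a. Of the 13 measured genes of secondary and tertiary granules, 5 were at least 2-fold higher, none was lower and 8 were neither, with a median log2 ratio of 0.51. Lcn2, Mmp8 and Chil3 stayed without their top cells, and Ngp and Retnlg did not. Retnlg, a resistin-like secreted protein, was 2.52-fold higher and the chitinase-like Chil3 2.23-fold (2.19 to 2.28). Of 12 measured genes of mature circulating neutrophils, 4 were higher (median 0.36), including the chemokine receptor Cxcr2 at 2.06-fold, the transcriptional repressor Mxd1 at 2.23-fold and Stfa2l1, of a gene family with near-identical copies, at 2.78-fold, but of the 4 the calls of Cxcr2 and Stfa2l1 ended without their top cells. Of 15 genes published for polymorphonuclear myeloid-derived suppressor cells (PMN-MDSCs), 4 were higher (median 0.26), including S100a9 at 2.71-fold and the lectin Clec4e at 2.08-fold, and 0 of the 4 stayed without their top cells. The share of neutrophil-like cluster 12 cells stood at 1.35% in naive and 4.80% in tumor-bearing blood beside these lists.

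The interferon response list lay on the other side in blood, with 1 of 28 measured genes at least 2-fold lower and a median log2 ratio of -0.20. Ifit3b, which shares sequence with Ifit3, was 2.08-fold (1.495 to 2.96) lower, or 1.96-fold without its top cell. Its call also ended with thinned cells, with means per cell, with equal mixes of clusters and in the largest cluster. Cluster 16, led by Ifit3b, Ifit3 and Ifit1, held 35 of 814 (4.30%, 3.01 to 5.93) naive and 5 of 354 (1.41%, 0.460 to 3.27) tumor-bearing blood cells beside this list. The antiviral gene Rsad2 (1.60-fold lower) and Cmpk2 (1.44-fold) did not reach 2-fold. None of 15 hypoxia and glycolysis genes reached 2-fold (median 0.20; Gapdh 1.41-fold and Ldha 1.31-fold higher). Against 10000 random lists of the same size and expression, the granule, mature neutrophil and PMN-MDSC medians lay above all and the interferon median below all. Other genes past 2-fold were the serine protease gene Prtn3 (2.44-fold higher), the lipid chaperone Fabp4 (2.06-fold) and the chemokine receptor Ccr1 (2.01-fold), and on the lower side the apolipoprotein Apoc1 (2.10-fold), the cholesterol synthesis enzyme Sqle (2.09-fold) and the antisense transcript Plxna4os1 (2.14-fold). The calls of Fabp4, Ccr1 and Apoc1 ended without their top cells, that of Apoc1 also with thinned cells. That of Sqle ended with thinned cells, with means per cell, with equal mixes of clusters, in the largest cluster and without the 2% of cells with the most UMIs. Apoe, another apolipoprotein, was 1.95-fold lower. Of the lists of other cell types, those of red cells, platelets, T and NK cells, and carcinoma or stromal cells had no measured gene in blood, and none of the 3 measured B cell genes reached 2-fold.

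Several of these differences were also present inside single clusters, compared by number. In cluster 0 of blood, with 97 tumor-bearing and 200 naive cells, Lcn2 was 15.2-fold (10.2 to 23.6) higher, Lrg1 8.91-fold (4.86 to 17.6) and Ifitm1 8.02-fold (4.95 to 13.6), and Lpl was 6.54-fold (4.31 to 10.4) lower. Inside the monocyte-like cluster 4 Wfdc21 was 57.8-fold (9.58 to 2360.1) higher, from 29 UMIs against 1, Ifitm1 5.57-fold (3.60 to 8.82) and Lcn2 4.27-fold (2.49 to 7.55). In cluster 2 Lrg1 was 6.96-fold (3.98 to 12.8) higher, whereas Lcn2 differed by 1.71-fold (1.17 to 2.48) and S100a8 by 1.02-fold (0.931 to 1.11). Because UMIs of 1 cell are not independent, these intervals are too narrow.

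Bone marrow posed the same question at the site where these cells are made, with 57 tumor-bearing and 153 naive cells. Bcl2a1a and Bcl2a1b, anti-apoptotic genes of a family with near-identical copies, were 6.86-fold (3.45 to 14.6) and 5.31-fold (3.59 to 7.98) higher in tumor-bearing bone marrow, Tppp3 was 3.24-fold (2.43 to 4.33) higher, the complement gene Cfb 3.25-fold (2.14 to 4.95), the receptor Cd244 3.22-fold (2.06 to 5.05) and the interferon-inducible GTPase Gbp2 2.94-fold (2.18 to 3.99). Lpl was 3.84-fold (2.39 to 6.53) lower, the membrane gene Ms4a7 3.94-fold (1.71 to 11.2), Upb1, an enzyme of pyrimidine breakdown, 7.22-fold (1.86 to 61.9), and Apoe 2.68-fold (2.44 to 2.94). Of 5505 measured genes, 74 were at least 2-fold higher and 104 lower, but libraries of this depth simulated with no difference gave a median of 97 such genes (range 77 to 117). Without the top cell of each gene 25 of the 74 and 50 of the 104 stayed. With all cells counted, the intervals of the 2 Bcl2a1 genes, Tppp3, Cfb, Cd244, Gbp2, Lpl and Apoe lay wholly past 2-fold. They cover counting error only, and the genes were named for their ratios or after their values were seen. Cfb had 17 of 56 UMIs in 1 cell, and was 2.31-fold higher without it. Scaled to the total without mitochondrial, ribosomal-protein and haemoglobin genes, 65 were higher and 148 lower, which moved the share on the higher side from 41.6% to 30.5%. Several leading genes rested on 1 cell. Bcl2a1a had 15 of 33 UMIs in 1 cell and was 3.82-fold higher without it, and Ms4a7 had 25 of 59 and was 2.29-fold lower. Bcl2a1b had 50 of 83 UMIs in 1 cell, and was 2.15-fold higher without it. Ccl5 was 42.4-fold (10.9 to 364) higher with 32 of 34 UMIs in 1 cell, the neutrophil-attracting chemokine Cxcl2 was at least 5.35-fold lower with 37 of 40 in 1 cell, and the glutathione synthesis gene Gclm was 3.61-fold (1.55 to 10.3) lower with 40 of 54. Ifitm1 was 3.81-fold (1.99 to 7.49) higher, or 1.80-fold without its top cell. The phosphatase gene Acp5 was 3.43-fold higher, and Cul4b, Bola1 and Qrich1 were 3.81-fold, 3.61-fold and 3.49-fold lower. Of the 16 genes named here by rank, 6 kept their calls with cells thinned to 5000 UMIs, 8 with equal mixes of clusters and 12 among cells called monocytes 1 by 1, and Bcl2a1a, Ccl5, Ifitm1 and Gclm were lost under each of these. Acp5, Upb1, Bola1 and Cxcl2 were lost with thinned cells and with equal mixes, and Ms4a7 and Cul4b with thinned cells.

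By lists in bone marrow, 0 of 15 granule genes were at least 2-fold higher, 1 was lower and 14 were neither, with a median log2 ratio of 0.45. Retnlg, higher in blood, was 2.47-fold (2.06 to 2.98) lower here, a call that ended without its top cell, while Prtn3 was 2.86-fold higher. Of 12 genes of NF-kB feedback and survival, 2 were higher (median 0.32), Bcl2a1b and Bcl2a1d, and none was lower. The call of Bcl2a1d ended without its top cell. No member of the endoplasmic reticulum stress list (10 measured, median 0.41) or of the non-classical monocyte list (9 measured, median 0.47) reached 2-fold. All 3 measured red-cell genes were lower, Hbb-bs 15.5-fold (5.18 to 76.3), Hba-a1 9.82-fold and Hba-a2 12.8-fold, at 4.86 against 75.3 CPM of Hbb-bs, and 0 of the 3 stayed without their top cells. Cluster 12 made up 9.15% of naive and 1.75% of tumor-bearing bone marrow cells beside these values.

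Spleen, a reservoir of monocytes, was compared between tumor-bearing and naive mice in the same way. The complement gene C1qa (chromosome 4, 136895917 to 136898803) was 12.04-fold (6.17 to 26.9) higher and C1qb 6.42-fold (4.03 to 10.8), with 73 of 141 C1qa UMIs in 1 cell and folds of 5.83 and 3.55 without the top cell. Vcam1, a vascular cell adhesion molecule also found on splenic macrophages, was 5.52-fold (3.52 to 9.06) higher. Among cells called monocytes 1 by 1 their log2 ratios were 1.74, 1.31 and 1.46, at levels under the minimum, and all 3 calls ended there and in the largest cluster. That of C1qa also ended with thinned cells and with means per cell, and those of C1qa and C1qb without the 2% of cells with the most UMIs. Of tumor-bearing spleen cells 2 of 579 were called macrophages, and 0 of 416 naive ones. The interferon-inducible Gbp2 (chromosome 3, 142620602 to 142638008) was 2.89-fold (2.53 to 3.32) higher, Gbp5 2.55-fold (1.85 to 3.56), and Fkbp5, a glucocorticoid-inducible co-chaperone (chromosome 17, 28399094 to 28517527), 3.79-fold (2.67 to 5.49). The call of Gbp2 ended in the largest cluster. Lpl was 2.49-fold (1.99 to 3.13) lower and the immediate early gene Fos 2.23-fold (1.96 to 2.54) lower.

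Of 5426 measured genes in spleen, 18 were at least 2-fold higher and 3 lower, where libraries simulated with no difference but counting error gave 0. Without the top cell of each gene 13 of the 18 and all 3 lower genes stayed, while C1qa, C1qb and Vcam1 then lay under 20 CPM in both libraries. Of 14 measured granule genes 3 were higher and none lower (median log2 ratio 0.17): Ngp at 8.46-fold (5.88 to 12.6), with 187 of 352 UMIs in 1 cell, the antimicrobial cathelicidin Camp at 3.77-fold (2.57 to 5.70) and Lcn2 at 2.46-fold (2.06 to 2.95), whose call ended without its top cell. Wfdc21 was 3.15-fold higher, Vcan 2.28-fold and Ifitm1 2.17-fold. Of 27 interferon genes 2 were higher, Gbp2 and Gbp5 (median 0.17). None of 15 PMN-MDSC genes reached 2-fold (median 0.21; S100a8 1.89-fold higher). Of 20 genes that handling of cells can induce, 1 was lower and 19 were neither, with a median of -0.22 below all 10000 random lists, and Jun and Hspa1a were 1.68-fold and 1.69-fold lower. Apoe was 1.81-fold lower and Chil3 1.72-fold higher. None of the 3 measured B cell genes reached 2-fold, and no gene of the red-cell, platelet, T and NK or carcinoma and stromal lists was measured. Cluster 12 shares were close, 3.85% and 3.97%.

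Over all 3 tissues, Ifitm1 was the gene at least 2-fold higher in each and Lpl the gene at least 2-fold lower in each, of 5019 genes measured in all. Independent lists of these sizes would share 0.000343 higher and 1.48e-05 lower genes, and libraries simulated with no difference but counting error shared 0. The call of Ifitm1 in bone marrow, with 14 of 26 UMIs in 1 cell, ended without that cell, with thinned cells and among cells called monocytes, where 0 genes were higher in all 3, and it also ended with equal mixes of clusters. At a threshold of 1.5-fold, 15 genes were higher in all 3, among them Vcan, Chil3, Serpinb1a, a neutrophil serine protease inhibitor, Cfb, Ccr1 and Dpep2, and 4 were lower, the lipid genes Apoe, Apoc1 and Lpl and the retinol dehydrogenase gene Dhrs3. These examples were chosen after their values were seen.

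**Figure D2:**
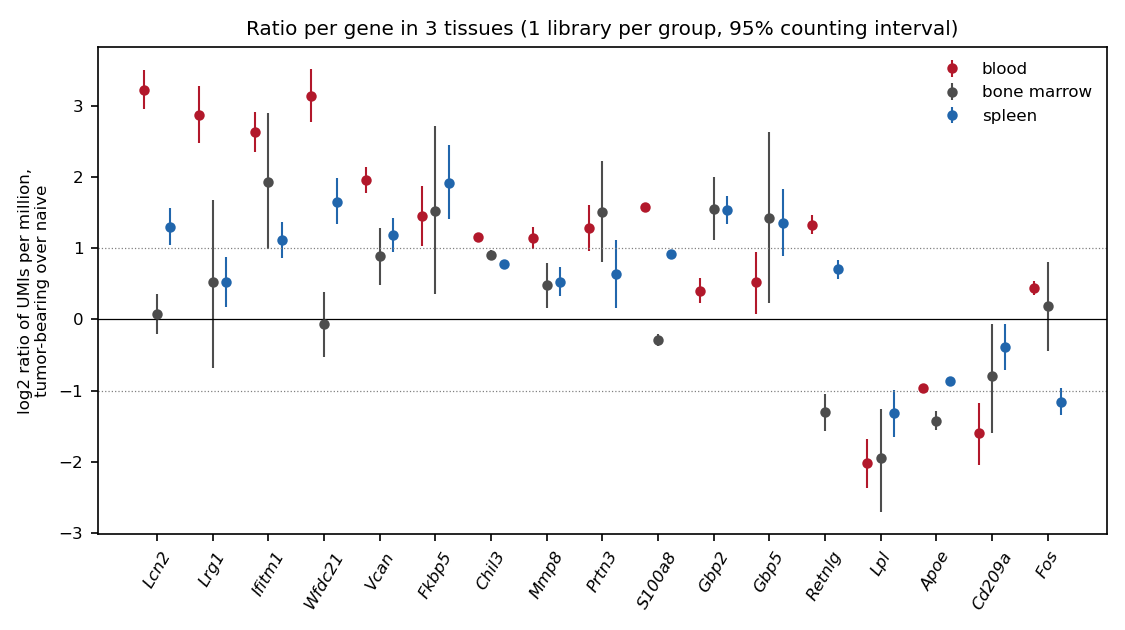
Log2 of the ratio of CPM, tumor-bearing over naive, for named genes in blood, bone marrow and spleen; points are ratios of 1 library to 1 library without pseudo-count, for genes chosen after their values were seen, bars are 95% counting intervals, and dotted lines mark 2-fold. Lcn2 lies farther from 0 in blood (9.39-fold) than in spleen (2.46-fold), and Lpl lies below the lower line in all 3 tissues.

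The comparison of tumor tissue with blood of tumor-bearing mice asked how the counted cells of the tumor differ from those of the blood. Genes of the cytokine and chemokine, tumor-associated macrophage and hypoxia lists stood higher in tumor tissue, and genes of the granule and non-classical monocyte lists lower. Beside the last 2 lists, the neutrophil-like cluster 12 held 4.80% of blood and 0.0522% of tumor tissue cells, and the monocyte-like cluster 4 18.1% and 0.156%. Spp1, the matrix cytokine osteopontin (chromosome 5, 104435118 to 104441050), was 6117-fold (1098 to 241620) higher, from 28186 UMIs against 1. The chemokine gene Cxcl2 (chromosome 5, 90903871 to 90905938) was 3281-fold (908 to 27096) higher. Arg1, encoding the arginine-degrading arginase (chromosome 10, 24915221 to 24927484), was at least 997-fold higher, the monocyte-attracting chemokine Ccl7 at least 569-fold, the angiogenic factor Vegfa (chromosome 17, 46016993 to 46032369) at least 506-fold, Rgs1, a regulator of G protein signaling, at least 366-fold, and the endocytic adaptor Dab2 at least 356-fold. Conversely, Retnlg was 62.5-fold (49.2 to 80.4) lower, the egress receptor S1pr5 41.5-fold (24.7 to 74.5), Ear2, an eosinophil-associated ribonuclease of a family with near-identical copies, 20.7-fold (17.4 to 24.9), the cytokine gene Il16 16.3-fold (13.6 to 19.7), Lcn2 19.5-fold (16.19 to 23.5) and S100a8 13.6-fold (12.998 to 14.2).

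Of 5648 measured genes, 614 were at least 2-fold higher in tumor tissue than in blood and 533 lower. With trimmed mean of M-values (TMM) factors the split was 764 to 350 (68.6% on the higher side against 53.5%), and the median log2 ratio of all measured genes moved from -0.13 to 0.06, so the ratios of this comparison are relative to that shift. Of 21 measured cytokine and chemokine genes, 19 were higher, none was lower and 2 were neither, with a median log2 ratio of 5.18. Ccl4 was 493-fold (193 to 1810.3) higher, the inflammatory cytokine Il1b 27.2-fold (25.6 to 29.1), Osm 108-fold and the T-cell-attracting chemokine Cxcl9 65.9-fold. Of 21 genes of tumor-associated macrophages 16 were higher and 1 lower (median 3.18), with C1qa 221-fold (143 to 363) and C1qc 67.1-fold higher. Of 22 hypoxia and glycolysis genes 18 were higher and none lower (median 2.07), including the lipid droplet gene Hilpda at 46.2-fold, Egln3, an oxygen-sensing prolyl hydroxylase, at 21.4-fold and Ankrd37 at 19.2-fold. Of 20 PMN-MDSC genes 12 were higher and 3 lower (median 1.74), with the prostaglandin synthase Ptgs2 486-fold and the lipopolysaccharide co-receptor Cd14 65.3-fold (55.9 to 76.7) higher. Ptgs2 had UMIs in 2 of 354 blood cells, so the size of its fold is loose. Of 17 checkpoint and inhibitory genes 11 were higher and 2 lower (median 1.41), among them Nt5e, the ectonucleotidase CD73, at 94.4-fold (16.9 to 3737), the lectin Clec4n at 15.2-fold and the ligand Pvr at 12.2-fold.

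Of 30 interferon genes 14 were higher and none lower (median 0.85), with Rsad2 at 12.8-fold, Cxcl10 at 12.4-fold and Oasl1 at 7.64-fold. Of 14 NF-kB feedback genes 7 were higher (median 0.999), Ier3 at 151-fold (118 to 196) and Tnfaip3 at 12.2-fold. Of 22 genes that handling can induce, 13 were higher (median 1.35), Fosb at 88.7-fold, Dusp1 at 12.3-fold, Atf3 at 10.9-fold and Jun at 7.71-fold, a fact that stands beside the chemokine and hypoxia lists. None of the 7 MHC class II genes (median 0.37; H2-Eb1 1.75-fold higher) and none of the 10 MHC class I genes (median 0.09) reached 2-fold. The MHC class II median was -0.06 without the tumor tissue cells of clusters 11, 13 and 17. Of 18 oxidative phosphorylation genes 1 was lower, Atp5k at 2.21-fold (median -0.23).

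Of 12 non-classical monocyte genes 9 were lower and 1 higher (median -2.52), with Ace 12.3-fold, Fabp4 15.1-fold and Eno3 9.91-fold lower. Of 13 granule genes 9 were lower and none higher (median -1.87). Ngp was at least 235-fold lower, although 1 blood cell held 150 of its 153 UMIs and the call ended without that cell, without cluster 12 and among cells called monocytes 1 by 1. Wfdc21 was 25.8-fold (19.4 to 35.0) lower and the gelatinase Mmp9 6.35-fold. Of 13 classical monocyte genes 3 were lower and 1 higher (median -0.66). Chil3, the haptoglobin gene Hp and the lysozyme gene Lyz1 were 3.67-fold, 4.13-fold and 2.47-fold lower, and Fn1, encoding fibronectin, was 2.04-fold higher. All 3 measured B cell genes were lower (median -2.33), Igkc at least 379-fold, Ighm 5.12-fold and Cd79b 3.84-fold. Of the platelet list only Pf4 was measured, at 279 CPM in tumor tissue and 48.5-fold higher than in blood. Pf4 is also a leading gene of the macrophage-like cluster 11 and a member of the macrophage list. No gene of the T and NK or the carcinoma and stromal lists was measured.

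**Figure D3:**
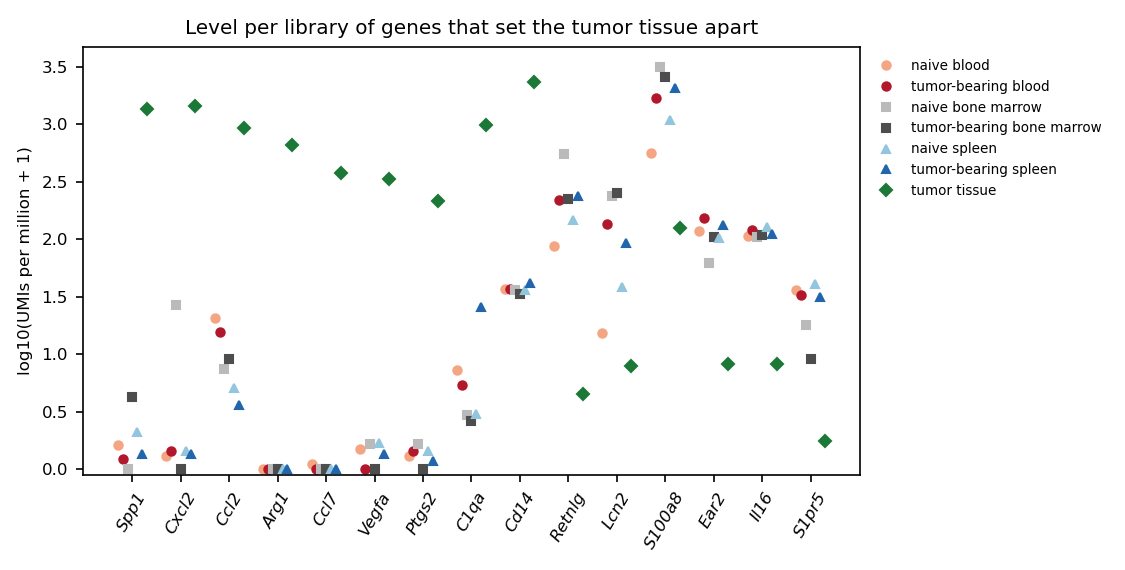
Level of named genes in each of the 7 libraries, as log10 of CPM plus 1 (vertical axis), each point being 1 library's summed value, for genes chosen after their values were seen. The tumor tissue point of Spp1 (1352 CPM) lies above those of the other libraries, and its points of Retnlg, Lcn2, S100a8 and Ear2 lie below them.

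Tumor tissue was also set against tumor-bearing spleen. Cxcl2 was 4172-fold higher, Spp1 3889-fold, Arg1 at least 1267-fold, Ptgs2 1235-fold, Vegfa 965-fold, Ccl7 at least 724-fold, the monocyte chemoattractant Ccl2 355-fold (215 to 635) and Ccl4 279-fold. Of these, Cxcl2 and Ptgs2 had UMIs in 1 spleen cell and Spp1 and Vegfa in 2. Their folds are near the floor, and their sizes cannot be ranked against the lower bounds. Slc40a1, encoding the iron exporter ferroportin, was 794-fold (141 to 31486) lower, with 68 of its 219 spleen UMIs in 1 cell. Among cells called monocytes 1 by 1 its levels lay under the minimum and its call ended. Ngp was at least 425-fold lower, Camp at least 189.6-fold, Retnlg 67.9-fold, S1pr5 40.1-fold, Wfdc21 26.8-fold, Ear2 18.2-fold and S100a8 16.7-fold. Pf4 was 1603-fold (288 to 63318) higher. Of 5752 measured genes 613 were at least 2-fold higher and 689 lower, against 806 and 456 with TMM factors (63.9% on the higher side against 47.1%), which moved the median of all genes from -0.15 to 0.07. Of 21 cytokine and chemokine genes 19 were higher (median log2 ratio 5.32, or 5.45 with genes at 0 UMIs set at their bound), of 22 macrophage genes 16 were higher and 1 lower (median 3.04), of 22 hypoxia genes 19 were higher (median 2.21) and of 22 handling genes 15 were higher (median 1.61). Of 14 granule genes 10 were lower (median -1.55) and of 10 non-classical monocyte genes 8 were lower and 2 higher (median -2.25).

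Against tumor-bearing bone marrow, 701 of 5745 measured genes were at least 2-fold higher in tumor tissue and 695 lower, where libraries simulated with no difference gave a median of 41 (range 29 to 56). With TMM factors the split was 930 to 389 (70.5% on the higher side against 50.2%), and the median of all genes moved from -0.17 to 0.08. C1qa was 605-fold (109 to 23886) higher and Spp1 418-fold (116 to 3449). Cxcl2 was at least 299-fold higher, Arg1 at least 136-fold, C1qc at least 128-fold, Ccl4 at least 89.8-fold, Ccl7 at least 77.7-fold and Vegfa at least 69.1-fold. Camp was at least 4813-fold lower, Ngp at least 4228-fold, the iron-binding lactoferrin Ltf 547-fold (225 to 1728), Retnlg 64.2-fold, Lcn2 36.6-fold, Wfdc21 34.3-fold, S100a9 22.98-fold and S100a8 20.8-fold. Of 7 MHC class II genes 5 were higher (median log2 ratio 1.71), unlike the comparison with blood, a contrast that was not tested. Of 21 cytokine and chemokine genes 18 were higher (median 4.83, or 3.58 with genes at 0 UMIs set at their bound), of 22 macrophage genes 16 were higher and 2 lower (median 3.30), of 22 hypoxia genes 18 were higher (median 2.14) and of 22 handling genes 17 were higher (median 2.33). Of 15 granule genes 12 were lower (median -2.43) and of 10 non-classical monocyte genes 8 were lower and 2 higher (median -1.49).

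In all 3 comparisons of tumor tissue, 499 genes were at least 2-fold higher and 339 lower, of 5416 measured in each. Independent lists would share 8.99 and 5.01 genes and simulated libraries with no difference 0, but part of the excess may come from the shared tumor tissue library. Genes with the largest minimum ratio on the higher side were Cxcl2, Arg1, Ccl7, Spp1, Vegfa, Ccl4, Dab2 and Ptgs2, and on the lower side Retnlg, Ngp, Wfdc21, S100a8, Il16, Ear2, Lcn2 and the acetyltransferase gene Nat8l (15.6-fold, 20.1-fold and 15.7-fold lower than in blood, spleen and bone marrow). The call of Nat8l against bone marrow ended with thinned cells.

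**Figure D4:**
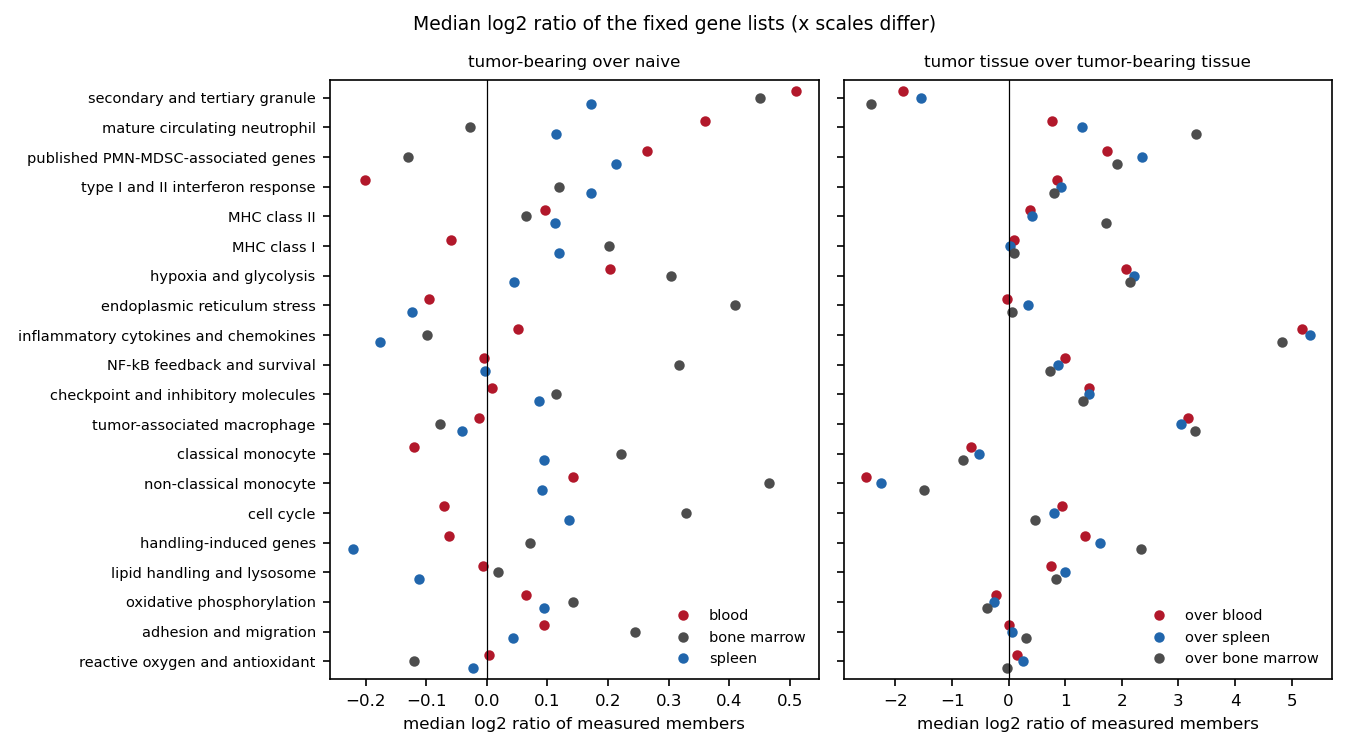
Median log2 ratio (horizontal axis, pseudo-count of 1 CPM) of the measured genes of fixed lists, tumor-bearing over naive in 3 tissues (one panel) and tumor tissue over tumor-bearing blood, spleen and bone marrow (the other), each point being 1 comparison of 2 libraries. The cytokine and chemokine list lies at 4.83 to 5.32 in tumor tissue and the granule list between -2.43 and -1.55.

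Surface antibodies were compared as shares of all antibody-derived tag (ADT) counts of a library. By these shares none of 47 antibodies differed by 2-fold between tumor-bearing and naive mice in any of the 3 tissues. By raw counts per cell all 47 were at least 2-fold higher in tumor-bearing blood. That library held a median of 6045 ADT counts per cell against 2350.5 in naive blood, a difference whose source was not tested. In blood, CD16.2, the Fc receptor encoded by Fcgr4, differed by 1.71-fold (1.68 to 1.74), at 1.87% against 1.10% of counts, beside an Fcgr4 RNA ratio of 1.72, followed by CD11b at 1.26-fold and CD97 at 1.22-fold, all higher in tumor-bearing blood. CD11b was 1.60-fold higher in bone marrow and 1.39-fold in spleen. CD115, the receptor of colony stimulating factor 1, was 1.53-fold lower in bone marrow and 1.37-fold higher in spleen, CD16.2 was 1.39-fold higher in bone marrow, and the stem cell antigen Ly-6A/E was 1.40-fold higher in spleen.

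Tumor tissue differed from tumor-bearing blood in 6 antibodies. CD16/32, Fc gamma receptors, was 3.31-fold higher, CD14 2.44-fold, the complement C5a receptor CD88 2.06-fold and the integrin chain CD18 2.05-fold, while CD115 was 4.77-fold lower and the adhesion receptor CD97 2.30-fold lower. The RNA of the matching genes was 65.3-fold higher for Cd14, 7.69-fold for C5ar1 and 2.31-fold lower for Adgre5, and did not reach 2-fold for Itgb2 (0.872-fold) or Csf1r (0.779-fold). In raw counts per cell CD14, CD88 and CD18 were instead lower than in blood (log2 ratios -0.26, -0.50 and -0.51), and none of the 4 higher antibodies reached 2-fold. By deposited values CD16/32 and CD14 stayed at 2-fold, and with median scaling CD16/32 alone. Tumor-bearing blood carried a median of 6045 ADT counts per cell and tumor tissue 1602. Against spleen, CD16/32 was 2.44-fold and CD11b 2.07-fold higher and CD115 4.08-fold lower. The call of CD16/32 ended by deposited values (log2 difference 0.65) and that of CD11b with median scaling (log2 ratio 0.93). Against bone marrow, the MHC class II antibody I-A/I-E and CD16/32 were both 3.39-fold higher, CD14 2.25-fold and CD18 2.01-fold, and CD115, CD97 and Ly-6C were 3.36-fold, 2.57-fold and 2.10-fold lower. The calls of CD14 and CD18 ended by deposited values, raw counts and median scaling, and I-A/I-E and CD16/32 stayed.

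**Figure D5:**
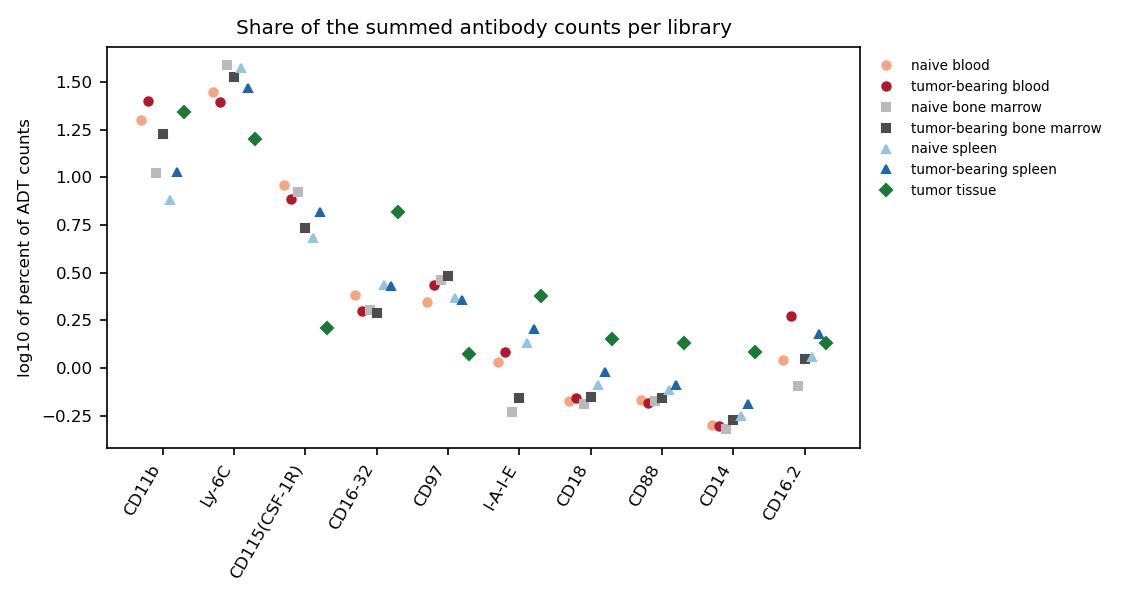
Share of each library's ADT counts (log10 of percent, vertical axis) held by named antibodies in the 7 libraries, each point being 1 library, with antibodies chosen after their values were seen. CD115 takes 1.62% of the counts in tumor tissue against 7.71% in tumor-bearing blood, and CD11b 21.9% against 25.1%.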

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

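The tests of Retnlg without cluster 12 and without its top cell were chosen only after the result was seen. With 1 library per group, no library could be compared with others of its group for standing far apart.

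Retnlg, the gene of a resistin-like secreted protein, stood on opposite sides in 2 tissues. Its log2 ratio of tumor-bearing to naive was 1.32 in blood and -1.30 in bone marrow, and the difference between the tissues was not tested. Without the neutrophil-like cluster 12, which it leads, the log2 ratio was 1.15 in blood and -0.43 in bone marrow. In neither tissue did Retnlg stay past 2-fold without its top cell.

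Cells that the metadata listed without gene counts entered no comparison but were not spread evenly over libraries. Of cluster 14, such cells made up 4.83% of all metadata cells in tumor-bearing blood (18 of 373) and 1.55% in naive blood (13 of 837). Of cluster 15, they made up 37.9% in tumor-bearing bone marrow (36 of 95) and 16.1% in naive bone marrow (30 of 186). Their genes could not be examined, and no explanation of their shares was tested.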

How the results depend on the processing

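Alternatives marked as added in the account of processing (cluster 12 left out, clusters 11, 13 and 17 left out, equal mixes, median-scaled antibodies, metadata denominator, top cell left out) were tests chosen only after the data were seen. Of the values that answer a comparison, 297 kept their side and stayed close (within 1.5 times for counts) and 129 did not. Of values of single genes and antibodies 631 stayed within their interval, 472 moved beyond it and 7 changed sign. The cause was not tested except where stated. No paired analysis was possible because each group held 1 library and no label tied libraries to animals. A minimum of 500 UMIs per cell was not run since it removes 0 cells, the authors' coarser clustering was not used here, as the planned change of resolution was for rebuilt clusters, and neutrophils, macrophages and dendritic cells could not be compared as classes. Depth limits bone marrow most, where the floor is 1.95 and 4.86 CPM and simulated libraries with no difference gave a median of 97 genes.

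With the stricter minimum of 100 UMIs and 50 CPM, by construction fewer genes were tested. Then 17 genes were higher and 1 lower in blood, 6 and 12 in bone marrow, and 7 higher in spleen. In tumor tissue 281 were lower than in blood, 354 than in spleen, and 453 higher and 346 lower than in bone marrow. No gene (0) was higher in all 3 tissues, and 191 were lower in all 3 tumor tissue comparisons. With no minimum except 1 UMI, which adds genes at the floor, 1186 were higher and 1311 lower in blood, 1124 and 1968 in bone marrow, and 1479 and 840 in spleen. The counts for tumor tissue were 3503 and 2342 against blood, 3151 and 2872 against spleen, and 4949 and 2049 against bone marrow. Shared genes were 55 and 56 over the tissues and 2460 and 901 over the tumor tissue comparisons.

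Without the top cell of each gene, 16 were higher and 4 lower in blood, 25 and 50 in bone marrow, 457 lower in tumor tissue than in bone marrow, and 0 higher in all 3 tissues. Ccl5 in blood turned to a log2 ratio of -1.88 and Gclm in bone marrow to 0.087, since 1 cell held most of their UMIs. In the largest cluster 58 were higher and 37 lower in blood and 55 and 38 in spleen, with Ccl5 at -1.01 in blood. Thinning to 5000 UMIs gave 12 lower genes in blood, 6 in spleen and 0 higher in all 3 tissues. Cells called monocytes gave 0 higher in all 3 tissues and Gclm at 0.044 in bone marrow. Means per 10000 gave 2 higher in all 3. At 1.5-fold 15 genes were higher and 4 lower in all 3 tissues, and 778 lower in all tumor tissue comparisons.

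With TMM factors 350, 456 and 389 genes were lower in tumor tissue than in blood, spleen and bone marrow, and 208 in all 3. With median-of-ratios factors they were 343, 439 and 425, and 211 in all 3. Both scale tumor tissue up against the other libraries, so that higher counts grow and lower counts shrink by construction. TMM moved list medians against blood to 3.37 for tumor-associated macrophages, 2.26 for hypoxia, 1.93 for PMN-MDSC genes, 1.61 for checkpoint genes, 1.55 for handling, 1.19 for NF-kB, 1.04 for interferon, 0.57 for MHC class II, 0.28 for MHC class I, -0.036 for oxidative phosphorylation, -0.46 for classical monocytes, -1.68 for granules, -2.33 for non-classical monocytes and -2.14 for B cells. Against spleen they were 5.55 for cytokines, 3.27 for macrophages, 2.44 for hypoxia, 1.84 for handling, -1.32 for granules and -2.04 for non-classical monocytes, and against bone marrow 1.97 for MHC class II.

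Without cluster 12 the granule median was 0.40 in blood and 0.55 in bone marrow. Without the tumor tissue cells of clusters 11, 13 and 17, medians against blood were 1.22 for handling, 1.01 for interferon, -0.063 for MHC class II, 0.15 for MHC class I, -0.27 for oxidative phosphorylation, -0.52 for classical monocytes and -1.56 for granules. Against spleen they were 2.54 for macrophages and -1.29 for granules, and against bone marrow 2.84 for macrophages, 1.47 for MHC class II and -2.10 for granules. With 20 bins the percentile of the oxidative phosphorylation median against blood was 16.97 (14.8 with 10).

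Raw ADT counts made all 47 antibodies 2-fold higher in tumor-bearing blood, beside its higher ADT counts per cell, whose source was not tested. Against blood, tumor tissue had 2 antibodies higher by deposited values, 0 higher and 21 lower by raw counts, and 1 higher and 4 lower with median scaling. Raw counts turned CD14, CD88 and CD18 to log2 ratios of -0.26, -0.50 and -0.51. Against spleen, 1 was higher by deposited values and 4 by raw counts, and 1 was higher and 2 lower with median scaling. Against bone marrow 2 were higher under each of these.

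Among cells of named clusters only, cluster 12 held 7.69% and 21.0% in naive and tumor-bearing blood, 93.3% and 33.3% in bone marrow, 19.5% and 23.5% in spleen and 0.518% in tumor tissue. For cluster 4 they were 92.3%, 79.0%, 6.67%, 66.7%, 80.5%, 76.5% and 1.55% in that order, and clusters 11 and 17 held 69.4% and 28.5% of tumor tissue. The bone marrow shares of clusters 12 and 4 rest on very few cells of named clusters, so no direction is drawn from them. Called 1 by 1, monocytes held 97.2%, 94.1%, 94.8%, 98.2%, 96.2%, 95.3% and 76.9%, neutrophils 3.92% of naive bone marrow and 0.574% of tumor tissue, and macrophages 18.4% of tumor tissue. Without the 2% of cells with the most UMIs cluster 11 held 5.22%.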

Other observations

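Several tests below were chosen only after the result was seen. They were those of the pooled neutrophil genes and of Ngp without cluster 12, and those without top cells. The count of bone marrow genes set against simulated libraries, with and without cluster 12, was also chosen then. So were the tests of free RNA with Chil3 set apart, with the limit on UMIs in 1 cell and the choice of clusters 0, 1 and 4. The same holds for the medians over all measured list genes and for the cluster and gene examples of the first 2 paragraphs.

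Inside the spleen, genes that stood higher in tumor-bearing mice were compared by cluster. In cluster 2, with 128 tumor-bearing and 73 naive cells, the complement gene C1qa was 59.0-fold (10.3 to 2351) higher, from 103 UMIs against 1, C1qb 11.9-fold (4.94 to 37.4), the adhesion molecule Vcam1 7.30-fold (3.57 to 17.4) and the interferon-inducible GTPase Gbp2 3.42-fold (2.83 to 4.15). Of these UMIs 1 cell held 73 of 103 for C1qa, 75 of 104 for C1qb and 44 of 102 for Vcam1, and without it C1qa stood at 30 UMIs against 1, C1qb at 29 against 5 (3.37-fold, 1.29 to 11.2) and Vcam1 at 4.199-fold (1.995 to 10.2). In clusters 0, 1, 4 and 6 the folds of Gbp2 were 1.25, 1.67, 1.31 and 1.30. Fkbp5, a glucocorticoid-inducible co-chaperone, was 9.97-fold (3.62 to 38.2) higher in cluster 0, 4.26-fold (2.16 to 9.33) in cluster 1, 2.10-fold (0.983 to 4.99) in cluster 2, 3.34-fold (1.34 to 9.91) in cluster 6 and 3.44-fold (1.52 to 8.77) in the monocyte-like cluster 4. Ifitm1 was 7.19-fold (3.65 to 16.1) higher in cluster 2 and 8.27-fold (3.01 to 31.7) in cluster 6, and stood at 0.854-fold (0.625 to 1.17) in cluster 0, 2.46-fold (1.65 to 3.77) in cluster 1 and 6.39-fold (3.69 to 11.9) in cluster 4. None of these differences between clusters was tested.

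Of 3 further lists described here for tumor tissue against tumor-bearing blood, that of lipid handling and lysosomes stood apart most from random lists of the same size and expression. Of 18 measured genes of lipid handling and lysosomes 7 were at least 2-fold higher and 2 lower, with a median log2 ratio of 0.75 at percentile 99.95. The lysosomal membrane gene Cd63 was 42.0-fold (26.5 to 70.9) higher, the cholesterol exporter Abca1 33.0-fold (18.4 to 66.3) and the protease Ctsl 9.15-fold (8.20 to 10.3). Of 19 adhesion and migration genes 5 were higher, 4 lower and 10 neither, with a median at percentile 69.2. The chemokine receptor Cxcr4 was 6.42-fold higher, and Itgal, the integrin chain of LFA-1, was 6.45-fold lower. Of 21 genes of reactive oxygen and antioxidant defense 5 were higher, 1 lower and 15 neither (median 0.15, percentile 93.2), with the sulfiredoxin gene Srxn1 8.71-fold (5.32 to 15.3) higher.

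Genes pooled from the neutrophil marker, granule and mature neutrophil lists stood higher in tumor-bearing blood and spleen. Not all are granule genes, since Cxcr2, Mxd1 and Ifitm1 are among the 12 of blood, and Chil3 is also on the classical monocyte list. Median log2 ratios were 1.35 and 1.53 over the 12 and 4 pooled genes picked for passing 2-fold. Over all 28 measured they were 0.62 and 0.26. Without the top cell of each gene 5 of the 12 and 3 of the 4 stayed past 2-fold, with medians of 1.02 and 1.27. With cluster 12 left out too, 4 and 3 stayed, with medians of 0.945 and 1.32. In bone marrow the secondary and tertiary granule list also had a median above all random lists, 0.45, with 0 of 15 genes past 2-fold higher and 1 lower. It stood so beside a cluster 12 share that was lower in the tumor-bearing library. A larger share of neutrophil-like cells may be part of the source in blood and spleen. Without cluster 12 the medians of the picked genes were 1.13 and 1.39, with 9 and 4 past 2-fold, and those of all 28 were 0.45 and 0.37. The picked genes thus did not rest on cluster 12 alone. Leaving out this cluster cannot exclude neutrophil-like cells as the source, since such cells may remain in other clusters. For Ngp in blood (log2 ratio then 0.27, from 2 UMIs in each library) a larger share cannot be told apart from 1 cell of cluster 12 that held 150 of 153 UMIs. Free RNA from neutrophils would add a like number of UMIs to every cell, which argues against it for Chil3, whose excess per cell was 54.5 (52.5 to 56.6) in cluster 0 and 9.12 (7.82 to 10.4) in cluster 4, a 5.98-fold spread beside a 1.18-fold difference in depth. For the other genes it cannot be told apart, since their excess relative to that of S100a8 and S100a9 spread 3.12-fold over clusters 0, 1 and 4 (11.97-fold with Chil3), but 1 cell held 48.2%, 80.7% and 34.2% of the S100a8 and S100a9 UMIs of these clusters. A response of monocytes to the tumor stays open as a hypothesis, beside a mouse or library effect with 1 library per group.

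Chemokine, inflammatory and hypoxia genes stood higher in tumor tissue than in blood (median log2 ratio 3.27 over all 43 measured list genes, and 3.74 over the 37 picked for passing 2-fold), beside a handling-induced list at 1.35. In the tenth of tumor tissue cells with the lowest share of handling transcripts (192 cells) the medians were 2.92 over all 43 and 3.505 over the 37. The handling list stood at -0.13 there, which follows from how these cells were picked. The genes thus stayed higher in cells low in handling transcripts. A low share does not show that a cell escaped induction by handling, so this cannot exclude it. Macrophage-like, dendritic cell-like and low-depth cells of clusters 11, 17 and 13 are not the whole source, as the medians were 3.35 and 3.89 without these clusters. Macrophages or dendritic cells in other clusters were not left out. Called 1 by 1, 353 of 1917 tumor tissue cells were macrophages and 69 conventional dendritic cells, while cluster 11 held 134, so such cells cannot be excluded as the source. Residence in the tumor is a possible explanation, but dissociation could also raise genes outside the handling list, which these values do not address.

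Bone marrow had more genes past 2-fold than blood or spleen, 178 against 37 and 21. Counting error of independent UMIs at its low depth is not the whole cause, since simulated libraries with no difference gave at most 117, with a median of 97. Without cluster 12, 159 genes were past 2-fold, 145 of them among the 178, so most calls did not rest on the cells of that cluster. Libraries simulated at that depth gave at most 116. All these simulations left out differences between cells, so being above them cannot tell a different share of cells from the sampling of few cells. Whether single cells with most UMIs of a gene account for the rest cannot be told apart from depth, because 75 genes were past 2-fold without top cells and that removal lowers counts by construction. A tumor effect may be part of the excess and was not tested apart from a library effect.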
